A study of Mus musculus with 2 samples.

How the data were processed

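The samples were 2 biological replicates of liver from mouse embryos of day 14.5, male and female pooled, each profiled by 1 H3K9ac ChIP-seq library. The labels describe 1 group, so no groups were compared. The files analysed were 4 peak lists in narrowPeak format and 2 text files that describe them, per the labels for genome build mm10. Per the file headers, replicate 1's list was made from its alignments and 2 further files, that of replicate 2 from its alignments and 1 further file, and the pooled list from the alignments of both and 2 further files, whose roles are not stated. The replicated list was derived from the other 3 lists, and its intervals are a subset of the pooled ones. The aligner, the peak caller, their versions and the thresholds are not given in the sources used here.

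Each peak carries a deposited enrichment, a linear ratio of signal over a background that is not stated, which was taken as the authors' value. It also carries a deposited −log10 p-value and a deposited −log10 q-value. The smallest −log10 p of the 4 lists lay just above 2, between 2.02 and 2.05, and the share of peaks with a q of at most 0.01 was 67.4% in replicate 1, 75.3% in replicate 2, 80.8% in the pooled list and 92.7% in the replicated list. Enrichment is not comparable between lists and was never averaged over replicates. The lists give neither read counts nor depth, so no interval depends on depth, and a weak or missing peak in a list cannot be told from low depth in that library.

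Peaks on the numbered chromosomes, X and Y were used, and 10, 7, 7 and 6 peaks of the 4 lists on other sequences were left out. Genes were the 21911 protein-coding genes of the GENCODE M21 annotation of GRCm38.p6, whose coordinates are those of mm10. A promoter was the window of 1 kb either side of any annotated protein-coding transcript start, and a gene counted as acetylated when a peak touched 1 of its windows. Its enrichment was that of its most enriched promoter peak. Neighbouring genes can share a peak, which is stated where the enrichment of such a peak is printed. Distal peaks lay over 2.5 kb from every annotated start. Overlap meant at least 1 bp. Coordinates are printed with the first base counted as 1.

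The lists, the tests, the motifs, the alternatives and the rule for named genes were fixed before the data were examined. The 26 gene lists were hepatocyte secreted proteins, liver transcription factors, coagulation and complement, postnatal hepatocyte metabolism, oncofetal and fetal growth, erythroid, globins, heme biosynthesis, blood stem and progenitor cells, megakaryocyte, macrophage, granulocyte, lymphoid, endothelial, mesenchyme and stellate, bile duct, other endoderm organs, neuronal, cardiac and skeletal muscle, germ cell, Hox, olfactory and vomeronasal receptors, ribosomal proteins, cell cycle, sterol and fatty acid synthesis, and housekeeping. Of their written members only Ahsp in the erythroid list had no match in the annotation. Alas2 belongs to both the erythroid and the heme list, and Hoxa9 to both the progenitor and the Hox list. Named genes were the first 3 members of each list, up to 2 further members with the highest enrichment and up to 2 further members without a replicated promoter peak, the 10 genes with the widest regions, the 10 promoters and the 10 distal peaks with the highest enrichment. Genes whose values are printed outside this rule are said to have been chosen after their values were seen.

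Observed overlaps and classes of place were set beside 100 random placements of peaks on the same chromosomes. Shares carry 95% exact (Clopper-Pearson) binomial intervals. Lists were compared with all other protein-coding genes by two-sided Fisher's exact tests, and the same test among acetylated genes was used for the widest 5% of regions, after peaks were joined across gaps of up to 1 kb. Counts of distal peaks within 50 kb of the gene's annotated 5' end were compared with 10000 random lists of acetylated genes. The permutation tests were two-sided, for lists with at least 3 acetylated members. Genes of a list are not independent replicates of one another, and neighbouring members share peaks, so these p-values describe lists of genes and not variation between animals. Motif matches on either strand were counted in distal peaks and in windows of the same width 5 kb to either side that met no peak, by the exact McNemar test. Benjamini-Hochberg adjustment ran over the 26 lists or the 12 motifs, with a threshold of 0.05.

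The alternatives were other promoter windows (500 bp and 2.5 kb), the gene's 5' end only, peaks with a q of at most 0.01, the 50% of peaks with the smallest p, the pooled list, each replicate's own list, a reciprocal overlap of 50%, lists of equal length, merged peaks, promoter CpG content as a covariate, other widths, distances and flanks (100 kb, 10 kb, the widest 10%), and the reversed consensus. Exact tests with CpG content used each member's acetylation probability from a logistic model of all genes. Copies of promoter sequence were counted as 32-base sequences with another exact match in the genome.

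Each statistic was tested on simulated data. Lists of which 95% of members were acetylated were called in 99.6% of cases, lists at 15% in 80.4% and unchanged lists in 1.3%, over 21911 genes. Over 10658 acetylated genes, lists with 30% wide members were called in 64.4% of cases and lists with doubled distal counts in 95% of cases, and unchanged lists in 0%. The simulated distal counts were Poisson draws made independently for each gene, whereas neighbouring genes share real distal peaks. The distal rates therefore may not hold for the real lists. Housekeeping genes, with a mean of 2.33 against 0.986 in random lists, were not called (permutation adjusted p = 0.345). In a single run the GATA motif was planted in 3000 random sequences, each with a probability of 15%. It was called, and the motifs not planted were not. Overlap counts equalled those of bedtools 2.31.1. The work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.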

Results

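Histone H3 acetylated at lysine 9 (H3K9ac), a chromatin mark of active promoters and of some enhancers, was profiled by chromatin immunoprecipitation and sequencing in mouse liver at embryonic day 14.5. At this stage the liver is the main site of blood formation, so the tissue holds hepatocyte precursors together with many developing red cells. The series had 1 group of 2 biological replicates, both from male and female embryos pooled, and no second condition. Peaks were called separately in replicate 1 (68142 peaks), in replicate 2 (28516 peaks) and on both replicates pooled (33424 peaks), and a replicated list of 26489 peaks was derived from those 3 lists. On the numbered and sex chromosomes these lists held 68132, 28509, 33417 and 26483 peaks, with median widths of 253, 478, 522 and 720 bp, and covered 36.4, 20.7, 28.7 and 27.1 Mb of build mm10. The lists hold no read counts, so the sequencing depth is unknown, and every interval printed here counts peaks or genes only. Enrichment is the authors' value for each peak and carries no error, and it was used only to describe or rank peaks within 1 list.

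The first comparison asked how far the peaks of the 2 replicates coincided. The strongest promoter peaks were present in both. Hmgb2, which encodes a chromatin protein of dividing cells, had the most enriched peak of the replicated list, at 60.4 (chromosome 8, 57511841 to 57514076, over the annotated start at 57511907), with 55.8 in the list of replicate 1 and 39.3 in that of replicate 2. The erythroid regulator Tal1 reached 50.4 (chromosome 4, 115054623 to 115064336), with 46.9 and 36.6 in the 2 replicates. Several liver genes had promoter peaks in replicate 1 and none in replicate 2. The promoter peak of Alb, the gene of albumin, had an enrichment of 5.63 in replicate 1, and the promoter windows of Hnf4a, a central hepatocyte regulator, held 4 peaks there with a highest value of 4.08. Afp, the gene of alpha-fetoprotein, had a promoter peak of 2.74 in replicate 1 and 1 in the pooled list. Peaks missing in replicate 2 were not confined to liver genes. The mesenchyme and stellate list had 8 acetylated members in replicate 1 and 1 in replicate 2, and the Hox list 5 and 0, while the erythroid list had 21 in both.

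Of the replicate 1 peaks, 22795 (33.5%, 95% exact binomial interval 33.1 to 33.8) overlapped a replicate 2 peak by at least 1 bp, against a mean of 1.53% and a highest value of 1.67% over 100 random placements. Of the replicate 2 peaks, 27335 (95.9%, interval 95.6 to 96.1) overlapped a replicate 1 peak, against a mean of 3.64% and a highest value of 3.89%. When peaks were ranked by their deposited significance into 10 groups of equal size, 100% of the top group of replicate 1, 98.5% of the next, 65.8% of the third and 3.29% of the last were overlapped. In replicate 2 the share was 100% in the top group and 85.0% in the last. The least significant peaks were short, with a median width of 172 bp in the last group of replicate 1 and 207 bp in that of replicate 2, against 1742 and 1675 bp in the top groups. Within 2.5 kb of an annotated start lay 32.6% of the last group of replicate 1 and 56.1% of that of replicate 2, against 96.8% and 98.6% of the top groups. With both lists trimmed to equal length the shares were 70.8% and 88.6%, and with a reciprocal overlap of 50% they were 23.2% and 55.5%. Of the pooled peaks, 79.3% (interval 78.8 to 79.7) were kept in the replicated list. The replicated peaks were overlapped by a replicate 1 peak in 98.7% of cases and by a replicate 2 peak in 81.5%, so that 4889 of them had no counterpart in the list of replicate 2.

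**Figure D1:**
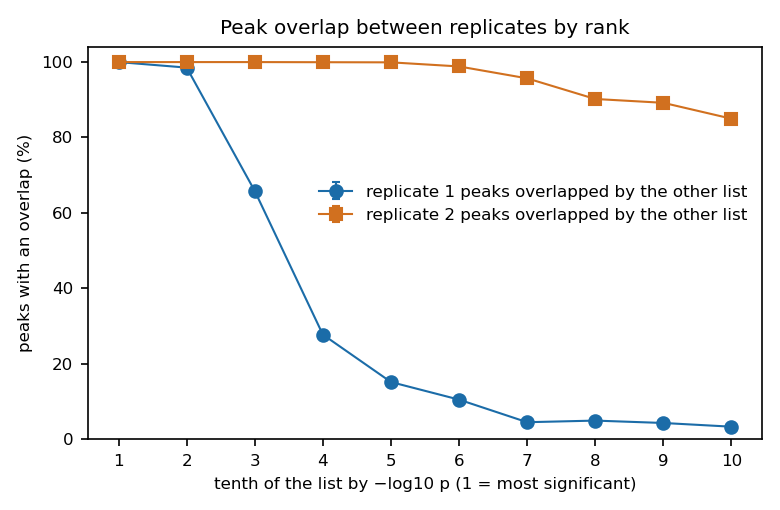
Percent of peaks overlapped by at least 1 bp by a peak of the other replicate, for 10 groups of equal size ranked by deposited significance (group 1 is the most significant), with 95% exact binomial intervals that are mostly smaller than the points. Replicate 1 falls from 100% to 3.29% and replicate 2 from 100% to 85.0%.

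The second comparison asked where the acetylated regions lie. They were concentrated at the starts of protein-coding genes. Of the 26483 replicated peaks, 14272 (53.9%, interval 53.3 to 54.5) touched the window of 1 kb either side of a protein-coding transcript start, against a mean of 3.91% and a highest value of 4.15% over 100 random placements, and these peaks held 69.5% of the covered length. A further 6.74% touched another annotated start, 26.7% lay in gene bodies and 12.6% between genes, where random placement gave means of 5.26%, 42.3% and 48.5%. Median enrichment was 10.8 at promoters and 4.32 at the 7942 distal peaks, which lay over 2.5 kb from any annotated start. The share at promoters depended on the list, at 28.2% in replicate 1, 55.4% in replicate 2 and 46.9% in the pooled list.

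**Figure D2:**
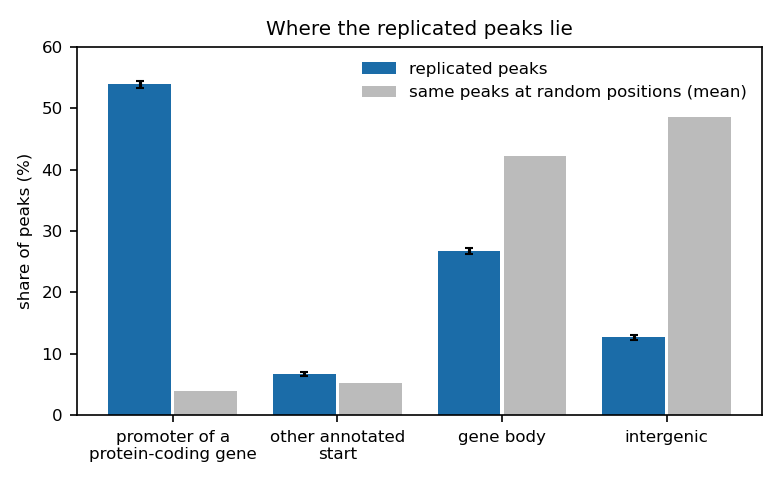
Percent of the replicated peaks in each of 4 classes of place (blue, with 95% exact binomial intervals) beside the mean of 100 random placements of the same peaks (grey). Promoters hold 53.9% of the peaks and 3.91% of the random ones.

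An acetylated promoter was found for 10658 of the 21911 protein-coding genes (48.6%), and for 11951 genes in the list of replicate 1 and 10274 in that of replicate 2. After Hmgb2, the most enriched promoters were those of Cbx3, encoding a heterochromatin protein (52.9, in a peak that also touches Hnrnpa2b1), Anp32e, a histone chaperone gene (50.8), Zc3h4 (50.5) and Tal1. Clk1 (48.4), Rnf139 (47.6), Ube2e3 (47.5), Fbxo30 (47.2) and Top1, the topoisomerase gene (46.9), completed the leading 10.

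The third comparison set the 26 gene lists fixed in advance against all other protein-coding genes. Genes of red cell formation had acetylated promoters almost without exception. The erythroid list was acetylated in 21 of its 22 annotated members, among them Gata1 (enrichment 23.1, chromosome X), Klf1 (39.5, chromosome 8, 84900348 to 84904072) and Epor, the erythropoietin receptor gene (36.0), and its median enrichment was 23.6. Slc4a1, which encodes the band 3 anion exchanger of the red cell membrane, reached 44.8 over its gene (chromosome 11, 102356436 to 102365242), with 28.7 in replicate 1 and 30.9 in replicate 2. All 9 genes of heme biosynthesis were acetylated with a median of 31.98, including Hmbs at 41.7 (in a peak that also touches H2afx), Fech, the ferrochelatase gene of the last step, at 40.8, and Alad at 31.98. All 8 globin genes were acetylated at a lower median of 6.66, from Hba-a2 at 19.3 to the embryonic gene Hbb-y at 3.52. By two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over the lists, the erythroid share of 95.5% (interval 77.2 to 99.9) differed from 48.6% of other genes (adjusted p = 1.32e-05), as did the heme list (adjusted p = 0.0026) and the globins (adjusted p = 0.00452). The 3 lists were also called in each replicate's own list, with 7 of 8 globins acetylated in replicate 2. Among the 50% of replicated peaks with the smallest p, 50% of the globins were acetylated and their call ended (adjusted exact p = 0.756). The erythroid member without a peak in any list was Slc25a37, the mitochondrial iron importer gene (chromosome 14, start at 69285112), where 100% of the 32-base sequences within 1 kb of the start have another exact copy in the genome. The corresponding percentages were 80.5 for Hba-a2, 74.4 for Hba-a1, 43.5 for Hbb-bt and 36.0 for Hbb-bs, so the values of these globin genes are uncertain.

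Genes of growth and of general cell upkeep were acetylated in full. Peaks stood at the promoters of all 76 ribosomal protein genes (median enrichment 22.3), all 20 cell cycle genes (24.6), all 20 genes of sterol and fatty acid synthesis (13.6) and all 15 housekeeping genes (21.8). Examples were Rps6 at 38.4, the proliferation marker gene Mki67 at 37.7, the mitotic cyclin gene Ccnb2 at 34.9, Actb at 33.1, and the cholesterol pathway genes Ldlr at 17.3 and Hmgcr at 14.5. The Fisher's exact tests gave adjusted p = 1.85e-23 for the ribosomal list, 2.83e-06 for both the cell cycle and the sterol lists, and 6.53e-05 for the housekeeping list. These calls were also made in each replicate's own list.

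Genes of the hepatocyte were acetylated unevenly and with low enrichment. Among genes of secreted hepatocyte proteins, 12 of 18 had an acetylated promoter, with a median enrichment of 4.56; Ttr, the transthyretin gene, had 5.49, Rbp4 had 5.15, Alb had 4.71 (chromosome 5, 90461520 to 90462026, within the gene close to its start) and Apoa1 had 2.63, whereas Afp, Apoc3 and Fgb had no replicated promoter peak. Of the liver transcription factors, 10 of 19 were acetylated with a median of 4.66, including Foxa3 at 11.5 (in a peak that also touches Sympk), the retinoid receptor gene Rxra at 8.59 and Cebpa at 3.02. Hnf4a, Foxa2, Nr1h4 and Onecut1 had no replicated promoter peak, although Foxa2 had 1 in replicate 1 (2.60), in replicate 2 (3.05) and in the pooled list. Oncofetal and fetal growth genes were acetylated in 10 of 15 cases, such as Igf2bp3 (21.6), Igf2bp1 (14.1) and Grb10 (12.01), but not Gpc3, Mest or Plagl1. By the same exact test these 3 lists did not differ from other genes (adjusted p = 0.196, 0.82 and 0.236). In the list of replicate 1 they did, with 15 of 18, 16 of 19 and 14 of 15 members acetylated (adjusted exact p = 0.0235, 0.0163 and 0.00551), against 10, 9 and 10 members in replicate 2. The secreted protein list was also called in the pooled list, with 77.8% (adjusted exact p = 0.0382). Among the 50% of replicated peaks with the smallest p, 0% of the secreted protein genes and 15.8% of the transcription factors were acetylated, below other genes (adjusted exact p = 0.000253 and 0.0411). With promoter CpG content as a covariate, the expected share of acetylated hepatocyte secreted genes was 25.5%, and the observed 66.7% was above it (adjusted exact p = 0.000295).

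A smaller share of genes of mature liver function carried the mark than of other genes. Among coagulation and complement genes 3 of 21 were acetylated, namely Proc and Masp1 (both 3.49, the latter in a peak that also touches Rtp4) and the prothrombin gene F2 (2.44), and Serpinc1, C3, F5 and F7 were not. Of the genes of postnatal hepatocyte metabolism only the glutaminase gene Gls2 was acetylated (5.15), which is 1 of 20; Cyp7a1, the rate-limiting enzyme of bile acid synthesis, Cyp2e1, Cyp3a11, Cyp8b1 and G6pc had no promoter peak in any of the 4 lists. For the member Cyp2c29, named after its value was seen, 92.1% of the promoter sequences have another exact copy, so its absence from the lists cannot be read as absence of the mark. Both lists were lower than other genes by Fisher's exact test (adjusted p = 0.0026 and 0.000128). The coagulation call was lost in the list of replicate 1, where 9 members were acetylated (adjusted exact p = 0.431), and both calls ended with CpG content as a covariate, where 14.0% and 17.0% of members were expected to be acetylated (adjusted exact p = 1 and 0.24).

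**Figure D3:**
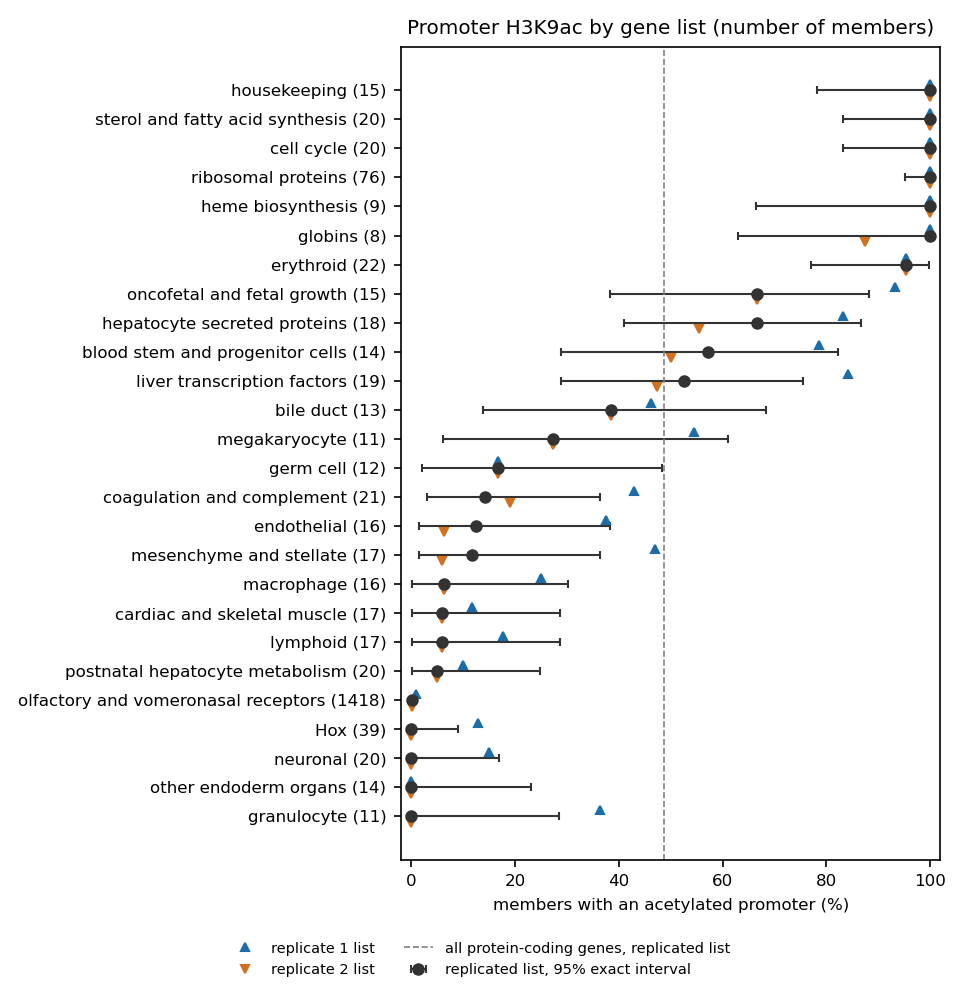
Percent of the members of each of the 26 gene lists that have an acetylated promoter, in the replicated list (black, with 95% exact binomial intervals) and in the lists of replicate 1 (blue) and replicate 2 (orange), with the number of members in parentheses. The dashed line is the 48.6% of all protein-coding genes, and 7 lists lie above and 12 below other genes by Fisher's exact test.

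Lists of other blood and supporting cell types of the tissue ranged from 0% to 57.1% acetylated members. In the list of blood stem and progenitor cells 8 of 14 promoters were acetylated, including Lmo2 (42.2), Runx1 (24.7), Myb (12.2) and Kit (6.69), but not Cd34 or Gata2. Megakaryocyte genes were acetylated in 3 of 11 cases, Gp9 (12.6), Gp1ba (8.31) and Itga2b (4.51), and bile duct genes in 5 of 13, with Notch2 at 16.5 and Aqp1 at 12.3, whereas Sox9, Krt19 and Epcam had no peak. These 3 lists did not differ from other genes by the exact test (adjusted p = 0.623, 0.258 and 0.623). Lower than other genes were the macrophage list with 1 of 16 (Spi1 at 2.07; adjusted exact p = 0.0011), the granulocyte list with 0 of 11 (adjusted exact p = 0.00188), the lymphoid list with 1 of 17 (Lck at 7.98; adjusted exact p = 0.000639), the endothelial list with 2 of 16 (Eng at 4.63 and Kdr at 3.16; adjusted exact p = 0.00599) and the mesenchyme and stellate list with 2 of 17 (Reln at 17.4 and Alcam at 4.16; adjusted exact p = 0.00379). In the list of replicate 1 the granulocyte, endothelial and mesenchyme lists held 4, 6 and 8 acetylated members and were no longer called (adjusted exact p = 0.288, 0.262 and 0.654). With CpG content as a covariate the macrophage and granulocyte calls ended (adjusted exact p = 0.676 and 0.221).

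Genes of tissues other than liver were rarely acetylated, and so were the Hox genes, of which Hoxa9 also belongs to the progenitor list. No replicated peak stood at the promoters of 14 genes of other endoderm organs, such as Pdx1, Cdx2 and Nkx2-1 (adjusted exact p = 0.000337), of 20 neuronal genes such as Snap25 and Neurod1 (adjusted exact p = 9.37e-06), or of all 39 Hox genes (adjusted exact p = 4.86e-11). A count of 0 leaves upper 95% limits of 23.2%, 16.8% and 9.03% for these shares. In the list of replicate 1, 0 of the endoderm genes, 3 of the neuronal genes and 5 of the Hox genes had a promoter peak, and all 3 lists stayed lower than other genes; in replicate 2 all 3 counts were 0. In the cardiac and skeletal muscle list 1 of 17 was acetylated, Mylpf at 32.2, in a peak that also touches the start of Tbc1d10b (adjusted exact p = 0.000639). Among 1418 olfactory and vomeronasal receptor genes 2 were acetylated (0.141%, interval 0.0171 to 0.509), and both peaks touch another gene's start as well, Ifi47 beside Olfr56 and Nt5c3 beside Vmn1r4; the list was also lower than other genes, but copies of its promoter sequences were not counted. Germ cell genes were acetylated in 2 of 12 cases, Rec8 (5.25) and Dazl (4.97), which did not pass the threshold (adjusted exact p = 0.0512); in the list of replicate 1 the same count did (adjusted exact p = 0.0235), and so did the pooled list (adjusted exact p = 0.0295) a promoter window of 500 bp, with 8.33% (adjusted exact p = 0.00874), the 50% of peaks with the smallest p, with 0% (adjusted exact p = 0.00288), and CpG content as a covariate (adjusted exact p = 0.0395).

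The fourth comparison concerned the width of the acetylated region around each promoter, with replicated peaks joined across gaps of up to 1 kb. The broadest regions lay over red cell genes and histone genes. The region of Ank1, encoding the red cell membrane anchor ankyrin, spanned 34207 bp (chromosome 8, 23027024 to 23061230, within the gene), that of Slc4a1 21503 bp, and a single region of 22366 bp held both Hba-a1 and Hba-a2. A region of 27730 bp on chromosome 13 (23737757 to 23765486) took in 9 of the 10 widest promoters, those of the histone genes Hist1h1a, Hist1h1c, Hist1h2ab, Hist1h2bb, Hist1h3a, Hist1h3b, Hist1h3c, Hist1h4a and Hist1h4b. The median over all 10658 genes was 1977 bp, and the widest 5% (533 genes) exceeded 5635 bp. Of the acetylated erythroid genes 16 of 21 were in that class, with a median width of 7470 bp, including Tal1 at 13293 bp, and of the heme genes 6 of 9, including Fech at 12976 bp and Hmbs at 11911 bp. By Fisher's exact test both lists were above other acetylated genes (adjusted p = 5.16e-16 and 1.46e-05). The globins, with 3 of 8, lay at the threshold (adjusted exact p = 0.04997), and the call ended in several settings, among them a promoter window of 500 bp, a q of at most 0.01, and when peaks were not joined, where 0 globins remained in the class. No other list was called, among them the cell cycle list with 0 of 20, the ribosomal list with 5 of 76 and the hepatocyte secreted list with 0 of 12.

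The fifth comparison counted distal replicated peaks within 50 kb of the 5' end of each acetylated gene of a list. Globin and erythroid genes had more of them than random acetylated genes. Acetylated globin genes had a mean of 14.6 distal peaks nearby, against 0.987 in 10000 random lists of the same size, and acetylated erythroid genes had 3.38 against 0.986. Tal1 had 8 such peaks, Gata1 4 and Slc4a1 3, while Klf1, Epor and Ank1 had 0. The count is centred on the 5' end even where the acetylated promoter lies elsewhere. That is so for Ank1 (5' end at 22974844), whose acetylated region lies within the gene, so its 0 does not describe that region's surroundings. In permutation tests adjusted over the lists these differences gave p = 0.0052 for the globins, the smallest value that the random lists can give, and p = 0.0078 for the erythroid list. Hepatocyte secreted genes had a mean of 0.167, liver transcription factors 0.5, heme genes 1.89, housekeeping genes 2.33 and bile duct genes 3, and none of these passed the threshold (permutation adjusted p = 0.479, 1, 0.949, 0.345 and 0.479). Neighbouring globin genes share their distal peaks, and with 1 member kept per cluster the globin list was too short to be tested. The erythroid call ended when the 50% of peaks with the smallest p were kept (mean 0.714, permutation adjusted p = 0.307) and when each peak had to be overlapped by both replicates (mean 1.95, permutation adjusted p = 0.0858).

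In the beta-globin cluster on chromosome 7, Hbb-y and Hbb-bs each had 22 distal peaks within 50 kb, the highest count among the named genes. Between the embryonic gene Hbb-y and the olfactory receptor gene Olfr66, which contains the locus control region known to drive the globin genes, 21 replicated peaks lay within 26.2 kb (103853217 to 103879442). The most enriched of them had 16.6 (103870047 to 103870889), and 21 and 20 of them were overlapped by peaks of replicates 1 and 2. This interval was chosen after its values were seen. Over all distal replicated peaks, 54.9% lay in introns, 36.3% between genes and 8.76% touched exons. The most enriched distal peak lay in an intron of Gabbr2 (29.7, chromosome 4, 46854228 to 46856520), followed by an intron of Arid1b (27.6, chromosome 17, 5189178 to 5190743) and a place between genes 12.7 kb from the start of Kpna2 (27.6, chromosome 11, 107011789 to 107012762). The next were nearest to Zfp869, Hectd1, Gse1, Itpr2, Tcf7l2, Aff1 and Hist1h4d, with enrichments from 27.4 down to 23.6, and all 10 were overlapped by peaks of both replicates.

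**Figure D4:**
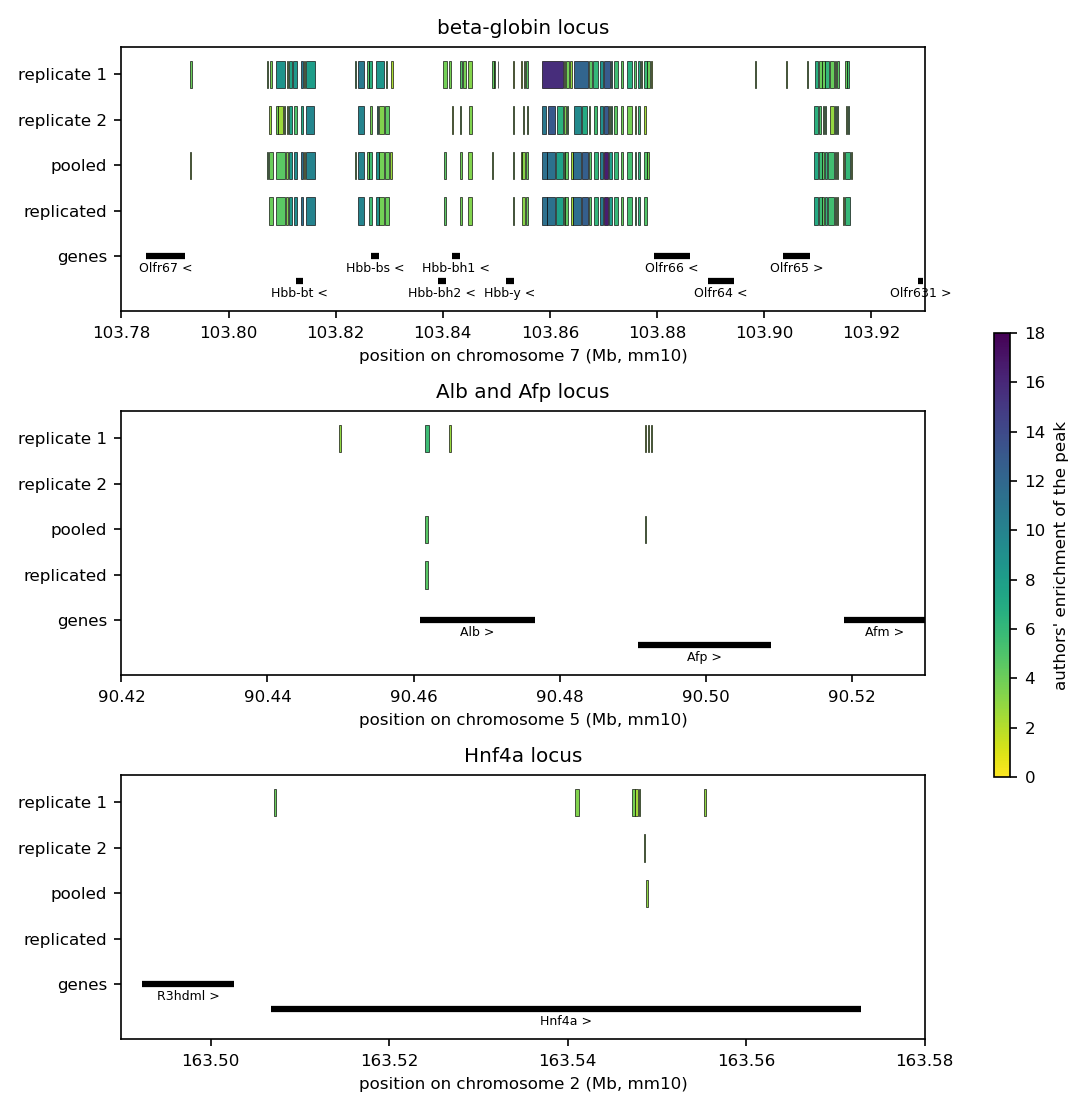
Peaks of the 4 lists around the beta-globin genes (top), Alb and Afp (middle) and Hnf4a (bottom), drawn to scale in mm10 and coloured by the authors' enrichment, which is not comparable between lists, with protein-coding genes as black bars. The beta-globin cluster holds peaks of up to 16.6 in the replicated list, whereas Alb has 1 replicated promoter peak of 4.71 and Hnf4a has none.

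The sixth comparison asked which transcription factor motifs were more frequent in 7540 distal replicated peaks than in flanking windows of the same width 5 kb away. The GATA motif, bound by the red cell regulator Gata1 and its relatives, was present in 20.95% of the peaks (interval 20.04 to 21.9) and 12.6% of the flanks, an odds ratio of 1.96. The motif of Krüppel-like factors such as Klf1 was present in 25.0% against 17.1% (odds ratio 1.77). The rarer ETS motif had the largest odds ratio, 3.41, with 1.31% against 0.385%. Smaller odds ratios were found for AP1, with 13.2% against 10.6% (1.32), and FOXA, the motif of the liver regulators Foxa1 to Foxa3, with 9.20% against 7.49% (1.27). The exact McNemar test gave adjusted p = 1.18e-45 for GATA, 8.21e-38 for KLF, 1.54e-09 for ETS, 5e-07 for AP1 and 0.000255 for FOXA. RUNX (14.0% against 15.5%, adjusted exact p = 0.0167) and NEUROD (13.2% against 14.5%, adjusted exact p = 0.0288) were less frequent in the peaks. The liver motif HNF4A (1.01% against 1.09%), CEBP (20.5% against 21.7%), NRF1 (0.133% against 0.0796%) and MEF2 (0.769% against 0.796%) did not pass (adjusted exact p = 0.825, 0.0782, 0.606 and 1), and HNF1 had no match in peaks or flanks, which allows a share of up to 0.0489%. GATA, KLF, ETS and FOXA were also higher in each replicate's own list, while in replicate 2 AP1 (8.47% against 7.50%), RUNX (9.71% against 10.7%) and NEUROD (9.49% against 10.2%) missed the threshold (adjusted exact p = 0.0653, 0.0743 and 0.24). The FOXA call ended when each peak had to be overlapped by both replicates (adjusted exact p = 0.0651), and CEBP was called less frequent in replicate 1 (10.5% against 11.2%, adjusted exact p = 0.00608) and in the pooled list (adjusted exact p = 0.0154). With flanks at 10 kb NRF1 was called more frequent (by 0.117 percentage points, adjusted exact p = 0.0201), as it was against the reversed consensus (by 0.133, adjusted exact p = 0.0026). Set against the reversed consensus in the same peaks, which has the same base composition, GATA, KLF and AP1 were more frequent. FOXA and ETS were less frequent by 2.96 and 1.67 percentage points, and RUNX, NEUROD, CEBP and MEF2 were more frequent. This comparison involves no flank, so it can reflect how common each word is and does not measure enrichment in peaks. RUNX and NEUROD, for example, were less frequent in peaks than in flanks but more frequent than their reversed forms. Reversal does not keep CpG: the reversed forms of CEBP and NRF1 hold more CpG than the motifs, and that of ETS holds less. For CEBP, NRF1 and ETS this comparison cannot be told from CpG frequency. Among the 50% of peaks with the smallest p only GATA, KLF and ETS passed the threshold.

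**Figure D5:**
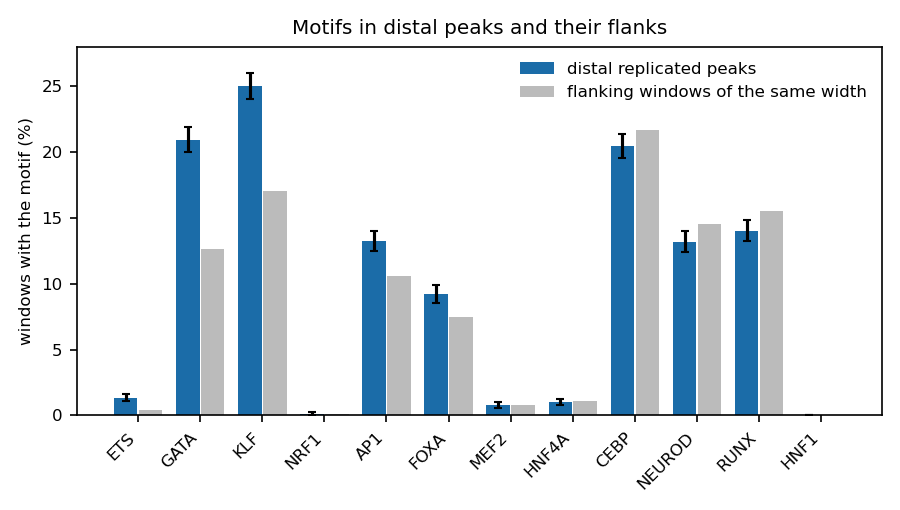
Percent of 7540 distal replicated peaks with at least 1 match to each motif consensus (blue, with 95% exact binomial intervals) and of the flanking windows of the same width 5 kb away (grey). GATA stands at 20.95% against 12.6% and KLF at 25.0% against 17.1%.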

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

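The tests of CpG content and of minority cell types, and the rank-matched comparison of peaks near liver and blood genes, were chosen only after the results were seen. The series has 1 group, so no biological explanation given by its design was tested.

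Some peaks lay outside the sequences or lists that the comparisons used. On unplaced or unlocalised scaffolds there were 10 peaks of replicate 1, 7 of replicate 2, 7 of the pooled list and 6 of the replicated list. Of the replicate 1 peaks, 34905 had no overlap in the pooled list; 66.3% of these were distal, with a median enrichment of 3.08 and a median width of 184 bp, and 44.6% had a q of at most 0.01. Of the replicate 2 peaks, 399 had no overlap in the pooled list, with 54.1% distal, a median enrichment of 3.28, a median width of 174 bp and 12.5% at a q of at most 0.01. There were 65 replicate 1 peaks that a replicate 2 peak overlapped and the pooled list lacked.

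The list of replicate 1 held 68132 peaks and that of replicate 2 held 28509. Weak distal replicate 1 peaks with and without a replicate 2 counterpart differed in median GC content by 0.888 percentage points (95% bootstrap interval 0.505 to 1.33), with 47.9% in 860 peaks and 47.0% in 20419. By the bound set beforehand this argues against a large base composition bias between the libraries among these peaks. The small difference lay above none, and promoter peaks and stronger peaks were not tested. A base composition bias as the cause of the longer list therefore stays open. A longer tail of weak peaks in replicate 1 cannot be told apart from a broader difference: 93.4% of the 39623 weaker peaks lacked a counterpart, but so did 29.2% of the 28509 most significant ones, between the bounds of 10% and 30% set beforehand. A different share of liver and blood cells in the 2 tissue pools also stays open, because 67.1% of 414 peaks near liver genes (secreted protein, transcription factor, coagulation and postnatal lists) and 56.9% of 764 near blood genes (erythroid, globin, heme and progenitor lists) lacked a counterpart, a difference of 10.2 points (interval 4.36 to 16.2) that met neither bound, and among peaks of equal rank the difference was −0.746 (interval −4.52 to 2.88). At promoters, 16 of 45 genes of the secreted protein, liver transcription factor and oncofetal lists with a peak in replicate 1 (35.6%) had no peak in replicate 2. This was more than the 14.2% of other genes (Fisher's exact p = 0.000294) but fewer than the 49.1% expected for genes of their rank (exact p = 0.0302). These lists had been called above other genes in replicate 1 and not in replicate 2. The difference from other genes therefore restates that loss and is no independent support. The coagulation list, with 9 acetylated members in replicate 1 and 4 in replicate 2, was not included. The comparisons with other genes and with genes of equal rank went in opposite directions and do not settle the question.

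Acetylated promoters of liver genes (secreted proteins and transcription factors) had a median enrichment of 4.61 in 22 genes, against 23.6 in 21 erythroid genes. Low CpG content of the liver promoters is argued against: their median CpG observed to expected ratio was 0.318, above the 0.258 of the erythroid promoters, and among promoters of like CpG content the median percentile was 91.5 for erythroid and 16 for liver genes, a difference of 75.5 (bootstrap interval 63 to 88). The unmatched percentiles were 84.6 and 8.49 (permutation p = 2e-05, the smallest that 100000 resamples can give). That liver cells are a minority of the cells in the tissue stays open as a hypothesis, since low rank does not single it out: the 9 acetylated promoters of 5 other cell type lists (Itga2b, Gp1ba, Gp9, Spi1, Lck, Kdr, Eng, Reln and Alcam) had a median percentile of 8.51 (interval 1.37 to 22.8), and 22 promoters with the progenitor and bile duct lists added had 16.0 (interval 7.90 to 31.3), but the germ cell genes Dazl and Rec8, of a cell type absent from liver, also had a median of 10.7, while the muscle gene Mylpf, whose peak also touches Tbc1d10b, stood at 96.7. No count of cells was analysed here, and weak acetylation within liver cells stays open too.

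The promoter of Slc25a37 had no peak in any of the 4 lists, although 21 of the 22 erythroid genes were acetylated. Of the 1970 sequences of 32 bases within 1 kb of its start, 100% had another exact copy in the genome, which is consistent with reads being shared with a near-identical copy and left out of the peaks. The other 21 erythroid promoters had a median of 1.32% and a highest value of 15.8%, at Gata1. Of 478 list genes checked, 3 reached 80%: Slc25a37, Cyp2c29 (92.1%, chosen after its value was seen) and Hba-a2 (80.5%), and Hba-a2 did carry peaks, so a copied promoter is not always without a peak. How reads with several matches were treated is not given in the sources used here, and the absence of acetylation at Slc25a37 cannot be inferred from these lists.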

How the results depend on the processing

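The restriction to replicated peaks overlapped by a peak of both replicates' lists and the restriction to 1 member per cluster were chosen after seeing the data; all other alternatives were planned. No paired analysis was possible because the series has 1 group. Of 80 values of the main results under the alternatives, 64 stayed the same and 16 moved. The cause was not tested except where the construction shows it.

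The overlap of replicate 1 peaks (33.5%) was 23.2% with a reciprocal overlap of 50%, 39.7% at a q of at most 0.01, 70.8% with lists of equal length, which drops the weaker replicate 1 peaks by construction, and 33.8% with merged peaks. That of replicate 2 peaks (95.9%) was 55.5%, 97.6%, 88.6% and 97.2%. The pooled peaks kept in the replicated list rose from 79.3% to 91.0% at a q of at most 0.01. The share of peaks at promoters (53.9%) was 78.7% among the 50% of peaks with the smallest p (the top 50%) and 28.2% to 55.4% in the lists of single replicates. Those lists gave 10274 to 11951 acetylated genes, 7 to 10 higher lists, 9 to 12 lower lists, 3 to 3 lists with wide regions, 2 to 2 with more distal peaks and 4 to 5 motifs above flanks. Lists with more distal peaks fell from 2 to 1 in the top 50%, with peaks in both replicates' lists, and with 1 member per cluster, which leaves too few globins to test. Motifs above the comparison went from 5 to 3 in the top 50%, to 8 against the reversed consensus and to 6 with flanks at 10 kb, where NRF1 was gained.

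A list share counted as the same when its direction against other genes and its call at the threshold were kept, even if the share changed. Hepatocyte secreted genes were the same in this sense at 66.7% and, in replicate 2 alone, 55.6%. By this rule 229 of 260 list shares stayed the same, 10 gained a call, 8 lost it and 13 changed direction against other genes. Liver transcription factors did so with the 5' end only (36.8%), the top 50% (15.8%), peaks in both lists (42.1%) and CpG content (52.6%, where the expected share rose). Progenitor genes did so with the 5' end only (42.9%), the top 50% (35.7%) and CpG content (57.1%), oncofetal genes in the top 50% (26.7%) and with CpG content (66.7%), and megakaryocyte genes with CpG content (27.3%) and in replicate 1 alone (54.5%), but not in replicate 2 alone (27.3%). Coagulation genes did so with CpG content (14.3%). Hepatocyte secreted genes fell to 0% in the top 50%, which by construction removes weak peaks. Without joining of peaks, 0% of globins had a wide region. Of 36 width results 30 kept their direction and call, whatever the share, 5 lost the call and 1 changed direction.

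A motif difference (peaks minus comparison, in percentage points) counted as the same when its sign and its call were kept, whatever its size. Of 96 such differences, 66 stayed the same by this rule, 4 gained a call, 8 lost it and 18 changed sign. HNF4A went to 0.0606 at a q of at most 0.01, 0.00914 in the pooled list, 0.135 in replicate 2 alone (−0.0152 in replicate 1 alone, no change of sign), 0.0194 with peaks in both lists, 0.143 with flanks at 10 kb and 0.305 against the reversed consensus. CEBP, called as less frequent in the pooled list (−1.25), went to 1.88 in the top 50%, 0.108 in replicate 2 alone (−0.697 in replicate 1 alone, also called) and 13.5 against the reversed consensus, which unlike the motif itself holds CpG by construction. NRF1 went to −0.0586 in the top 50% and −0.0269 in replicate 2 alone (0.0213 in replicate 1 alone), but was called as more frequent with flanks at 10 kb (0.117). It was also called against the reversed consensus (0.133), which holds more CpG than the motif by construction. MEF2 went to 0.0213 in replicate 1 alone (−0.0538 in replicate 2 alone), 0.0194 with peaks in both lists and 0.332 reversed. Against the reversed consensus FOXA was at −2.96, ETS at −1.67, RUNX at 4.39 and NEUROD at 8.61. No flank enters that comparison, so its signs can reflect how common each word is and do not reverse the differences from flanks. The reversed ETS consensus lacks the CpG of the motif by construction, so the ETS value cannot be told from CpG frequency. Of 23 distal counts 21 kept their direction and call. For named genes with a promoter peak, 671 of 774 enrichments equalled the main value or differed by less than the standard deviation of the replicates' enrichments. That rule sets values of different lists side by side, although enrichment is not comparable between lists. Settings in which such a gene had no promoter peak gave no enrichment and are not among the 774. For named genes without a replicated promoter peak, 736 of 765 peak counts were unchanged. Depth is unknown, so how much of this follows depth could not be examined.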

Other observations

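The gene families tested here were chosen after the data were seen, with Fisher's exact tests adjusted over 23 families and without CpG content as a covariate. Genes of basic cell machinery outside the fixed lists were acetylated nearly in full. All 78 genes of the mitochondrial ribosome had an acetylated promoter (adjusted exact p = 3.84e-24), as did 36 of 37 genes of respiratory chain complex I (2.33e-10), 36 of 39 proteasome genes (1.74e-08), 32 of 37 genes of ubiquitin-conjugating enzymes (3.89e-06) and 10 of 11 splicing factors of the SR family (0.00598), all by exact test. Replication-dependent histone genes, which are active in dividing cells, were acetylated in 61 of 67 cases at a median enrichment of 25.5 (adjusted exact p = 5.07e-13). Of the zinc finger genes named Zfp, 307 of 391 were acetylated (78.5%, interval 74.1 to 82.5; adjusted exact p = 5.21e-33).

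Families of differentiated epithelia and of adult metabolism mostly had no promoter peak, but copies of promoter sequences were counted only for members of the fixed lists, so missing peaks in families of similar genes may not mean missing acetylation. Low CpG content of their promoters was not examined either. Among the fixed lists, the low calls of coagulation and postnatal metabolism genes ended with CpG content as a covariate, while those of neuronal and Hox genes stayed. Of 94 cytochrome P450 genes 7 were acetylated (7.45%, adjusted exact p = 2.75e-17), of 21 UDP-glucuronosyltransferase genes 1 (adjusted exact p = 2.85e-05) and of 61 serpin genes 6 (adjusted exact p = 2.67e-10). Among 49 keratin genes the acetylated ones were Krt8 and Krt18, the pair of simple epithelia that hepatocytes carry, and Krt10 (adjusted exact p = 2.33e-10), chosen after their values were seen. No promoter peak was found for 57 genes of keratin-associated proteins, 64 defensin genes, 35 bitter taste receptor genes or 19 Wnt ligand genes. Among 56 clustered protocadherin genes 1 was acetylated, among 44 collagen genes 1 (Col18a1, chosen after its values were seen), among 81 potassium channel genes 5, among 35 chemokine genes 3 and among 37 interleukin genes 2, and each of these families was lower than other genes by the exact test, the highest adjusted p being 7.75e-07, for the chemokines. Solute carrier genes (179 of 371), Fox factors (17 of 44) and Sox factors (5 of 19) did not pass (adjusted exact p = 0.917, 0.237 and 0.0715).

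Starts of long intergenic noncoding RNA genes carried a replicated peak within 1 kb in 231 of 5117 cases (4.51%), antisense genes in 3.95%, microRNA genes in 2.31% and processed pseudogenes in 0.621%. By chromosome, the share of protein-coding genes with an acetylated promoter was 32.5% on X (308 of 948) and 1.09% on Y (2 of 183), and among the others it ran from 39.0% on chromosome 14 to 58.0% on chromosome 12. Copies of promoter sequences were counted only for the fixed lists, and male and female embryos were pooled. The low shares of X and Y may therefore not mean missing acetylation.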
